A study of Mus musculus with 75 samples.

How the data were processed

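Polyadenylated RNA was sequenced from mouse embryonic fibroblasts that lack p53, c-Rel and RelA and that carried a pBABE-puro retrovirus, either empty (EV) or encoding RelA or a RelA mutant. RelA is the NF-kB subunit with the C-terminal transactivation domains TA1 and TA2. Per the labels' protocols, cells were kept overnight in 0.5% serum and then received 10 ng/ml of tumor necrosis factor (TNF), and RNA was taken before TNF and after 0.5, 1, 3 and 8 h. Stranded libraries were made from 1 µg of total RNA with 12 PCR cycles and read as 50-base single ends, per the labels' protocols. The 75 libraries form 55 groups of construct and time. The 20 groups of EV, RelA-WT, RelA-dTA1 and RelA-dTAD hold 2 libraries each, 1 from each of the 2 deposited sets. The other 35 groups, from 7 constructs, hold 1 library each. RelA-DB and RelA-dCterm belong to set 1, and RelA-TA2_CI, RelA-TA2_S467A, RelA-TA2_CI_S467A, RelA-TA2_CI-dTA1 and RelA-TA2_CI_S467A-dTA1 to set 2.

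The deposited values were read counts per gene. Per the submitters' processing notes, the authors trimmed reads with cutadapt 1.9.1, aligned them with STAR to mm10 and made the counts with featureCounts 1.5.0, and DESeq2 is named there as well. The strand setting of the counting is not stated, so overlapping and antisense genes are uncertain. Paralogs with near-identical sequence (families such as Zfp, H2, Ifit, Oas, Gbp and Serpina3) share reads and are uncertain too. Each deposited table held 45706 gene entries, of which 45143 (98.77%) had a symbol in the reference gene table and 16412 had no read in any library. All gene entries and all sample columns were used. Coordinates are 1-based mm10 positions from the reference annotation, whose gene version equals the deposited one for 58.0% of identifiers, so the ends of a gene can differ slightly from those used in counting.

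CPM values (cpm function of edgeR) were computed from the deposited counts with library sizes scaled by the trimmed mean of M values in edgeR 4.0.16 under R 4.3.3, and log2 values from them carry a prior count of 2. Library totals were 4422396 to 6915919 counted reads in the 30 libraries of set 1 and 10440202 to 22908738 in the 45 libraries of set 2. Between 15684 and 17288 genes had a read in a library of set 1 and between 17821 and 20055 in set 2. The gene entry Gm42418, which collects ribosomal RNA reads, took 0.001% to 0.01% of the reads in set 1 and 0.117% to 3.21% in set 2. For a group whose libraries all had 0 reads of a gene, a fold was given as a bound from a floor of 3 reads over the group. For 1 to 3 reads, the ratio of counts was given with its 95% interval (exact conditional binomial). PCR copies are not independent molecules, so these intervals and floors cover counting error only.

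The tests and comparisons of this paragraph were fixed before the data were examined, with these exceptions. Added later were the average response within a construct, differences between constructs at single times, comparisons of lone-library constructs with EV or RelA-dTAD, and unstimulated levels against EV. So were the fits without 8 h, the tests on zinc finger genes and on Rela, the random lists for interferon genes and the correlations across constructs. Genes passed edgeR's filterByExpr, which left 13665 genes in the 40 libraries of the 4 replicated constructs and 15090 in all 75. A negative binomial model with 1 mean per construct and time was fitted to the 40 libraries and tested with edgeR's quasi-likelihood test (robust), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. It has 20 residual degrees of freedom and a common dispersion of 0.0224. The comparisons were TNF against 0 h in each construct (any time, each time, and the mean of the 4 TNF times), the difference of these TNF responses between constructs, and the unstimulated levels. A second fit of all 75 libraries compared the TNF response of each single-library construct with RelA-WT. It also tested the averaged effect of the CI, S467A and dTA1 changes over 3 backgrounds each. In this fit the replicated constructs pool both sets, while each lone construct comes from 1 set. The spread of the fit comes from the replicated groups, so the lone libraries are assumed to vary like those. The single-library constructs have no replicate check of their own. For them, the median difference of the NF-kB target list from RelA-WT of the same set is given with its percentile among 10000 random lists of equal size matched on expression in 20 bins, as a description of these libraries. The labels do not say whether replicates are separate cultures, so p-values measure only the spread between these libraries.

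Replicate numbers follow the sets, per the labels. In 190 pairs of groups, the deviations of same-numbered libraries from their group means correlated at 0.357 to 0.668 (median 0.526), and the principal component that separates the sets held 15.1% of the variance. The numbers thus pair the samples. A fit with the set as a block, called the replicate block, is given beside a result as the blocked value. This is done where it changes a call or moves a count by more than 1.5 times. Its common dispersion was 0.00381 in the 40 libraries.

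The 21 gene lists cover NF-kB targets, NF-kB feedback and signalling, chemokines, cytokines and growth factors, adhesion and complement, the interferon response, MHC class I presentation, immediate early genes, matrix proteases and inhibitors, survival and redox, p53 targets, the cell cycle, glycolysis and hypoxia, cholesterol synthesis, the unfolded protein response, fibroblast matrix and identity, and markers of macrophages, endothelium, epithelium, muscle and neurons. Some genes stand in more than 1 list, and 1 listed symbol (Rigi) had no match. Lists were tested with camera in limma 3.58.1 (preset correlation 0.01) and again with an estimated correlation, both adjusted over the lists of a comparison. Both list tests given here used the design without the replicate block, so they leave out the pairing. The difference between sets thus enters the estimated correlation. List counts are given over all genes tested and adjusted over the list alone.

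Named genes followed a fixed rule. It took the targeted genes Rela, Rel and Trp53 in every construct and a panel of 21 genes. Per comparison it added the 5 highest and 5 lowest log2 fold changes among genes with an adjusted p under 0.05, a mean of at least 1 CPM and the same sign in both sets, and up to 4 members per list with the smallest p. Genes named outside this rule are marked in the text.

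The procedure was tested on simulated counts with 200 changed genes drawn on the real means and library sizes. For EV against RelA-WT (13415 genes), 79% of 2-fold and 96% of 4-fold changes in response were recovered, and 9 calls (4.89%) were false. For RelA-DB against RelA-WT (13656 genes) these shares were 57% and 94%, with 13 false calls (7.93%). The changed genes were drawn only among well-expressed genes, each with the same change at all TNF times, and without a difference between sets. Simulated lone libraries had the dispersion of the replicated groups, so that assumption was not tested. These shares hold only for such conditions. Alternatives were the replicate block, size factors of DESeq2 1.42.0 in edgeR, DESeq2 itself (40 libraries only), no filter on low counts, a minimum of 2-fold, leaving out each replicate in turn, and for list medians another prior count (0.5), single times, another reference and other gene choices. Samples could not be regrouped at random within groups, since none holds more than 2 libraries.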

Results

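The data are RNA sequencing counts from 75 libraries of mouse embryonic fibroblasts without p53, c-Rel and RelA. The cells had received an empty vector (EV), wild-type RelA (RelA-WT) or a RelA mutant and were sampled before TNF and after 0.5, 1, 3 and 8 h of it. EV, RelA-WT, RelA-dTA1 (without TA1) and RelA-dTAD (without the transactivation domains) had 2 libraries at each time, and 7 further mutants had 1. Libraries held 4422396 to 6915919 counted reads in set 1 and 10440202 to 22908738 in set 2. Levels are means ± SD in CPM over 2 libraries, or the value of the lone library. Changes are log2 fold changes ± SE, and an average response is the mean of the 4 TNF times against 0 h. No cells kept without TNF were sampled at the later times, so a TNF response includes any change with time alone. Counts of genes are at an adjusted p under 0.05, and blocked values come from the fit with the replicate block.

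The level of Rela, the gene put back, was compared across constructs to see what each line expressed. Before TNF, Rela (ENSMUSG00000024927.7, mm10 chr19:5637483-5648130) stood at 16.2 ± 0.821 in EV, 1311 ± 229 in RelA-WT, 1459 ± 477 in RelA-dTAD and 1149 ± 428 in RelA-dTA1. EV lay below RelA-WT by a log2 of -6.36 ± 0.44 (adjusted p = 1.68e-09). At 8 h Rela was at 5270.2 ± 1962 in RelA-dTAD, a log2 change of 1.87 ± 0.35 (adjusted p = 1.13e-04), and rose in RelA-dTA1 as well (0.93 ± 0.34, adjusted p = 0.0378). It stood at 1628 ± 205 in RelA-WT and 27.8 ± 3.67 in EV, where the change was 0.81 ± 0.38 (adjusted p = 0.0853, blocked 0.0464). In the single libraries Rela before TNF ran from 531 in RelA-dCterm and 658 in RelA-DB to 1443 in RelA-TA2_CI. Rel (ENSMUSG00000020275.9, chr11:23736847-23770970), which encodes c-Rel, was at 23.01 ± 5.94 in EV, 23.02 ± 5.89 in RelA-WT, 19.2 ± 3.91 in RelA-dTAD and 21.3 ± 7.04 in RelA-dTA1, and at 19.6 to 30.5 in the single libraries. Trp53 (ENSMUSG00000059552.11, chr11:69580359-69591873), which encodes p53, was at 35.2 ± 5.18, 37.1 ± 5.89, 36.2 ± 3.02 and 34.4 ± 4.77 in the same 4 groups, and at 26.3 to 45.0 in the single libraries. Counts over a whole gene include exons outside a deleted part, so the Rel and Trp53 values check no knockout, and Rela reads do not separate vector from chromosome.

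**Figure D1:**
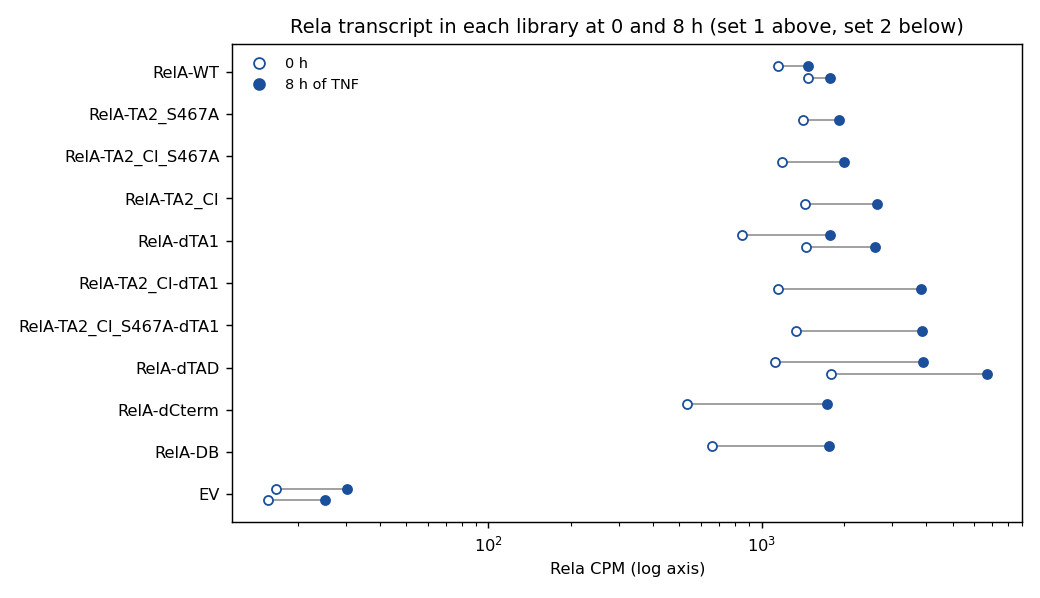
Rela level in CPM (log axis) for each construct before TNF (open symbols) and after 8 h (filled symbols), 1 symbol per library, with set 1 drawn above set 2. EV lies near 16.2 ± 0.821 before TNF and RelA-WT near 1311 ± 229.

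The TNF course in RelA-WT asks which genes the restored protein's cells turn on and off. Within 0.5 h Tnfaip3, whose product A20 ends NF-kB signalling, went from 22.1 ± 5.97 to 699 ± 35.1 CPM. Nfkbia, which encodes the inhibitor IkBa (chr12:55489411-55492647), went from 49.1 ± 1.92 to 739 ± 23.5 and to 1022 ± 79.7 at 1 h. The neutrophil chemokine gene Cxcl2 had 1 read before TNF and 373 at 0.5 h, a ratio of 377 (95% interval 67.2 to 14900). Irf1, a transcription factor of the interferon system, reached 947 ± 1.13 at 1 h from 54.8 ± 1.32. The leukocyte adhesion genes Vcam1 and Icam1 were at 2669 ± 137 and 692 ± 129 at 3 h, from 233 ± 39.3 and 11.8 ± 1.09. Cxcl9, a T cell chemokine gene, was at 209.6 ± 26.3 at 8 h, from 1.19 ± 0.126.

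On average over the 4 times, Nfkbia rose by 3.66 ± 0.14 (adjusted p = 8.50e-15), Tnfaip3 by 4.48 ± 0.32 (adjusted p = 4.88e-10) and Irf1 by 3.24 ± 0.15 (adjusted p = 2.44e-13). Ccl20, a chemokine gene for lymphocytes and dendritic cells, rose by 5.38 ± 0.39 and Sele, which encodes E-selectin, by 5.34 ± 0.44. A gene with very few reads at 0 h was Cd83, a dendritic cell marker (562 reads at 3 h against 3, ratio 231, 95% interval 78.6 to 1120). Another was Mir155hg, the host of the microRNA miR-155 (237 reads at 1 h against 2, ratio 129, 95% interval 35.3 to 1070). The inflammatory cytokine gene Il6 rose by 4.598 ± 0.54, Ccl2 by 3.83 ± 0.38, Ccl5 by 1.95 ± 0.17 and the macrophage growth factor gene Csf1 by 1.901 ± 0.16. Rela itself moved by 0.12 ± 0.27 (adjusted p = 0.883) and Rel by 0.34 ± 0.17 (adjusted p = 0.263, blocked 0.0377), while Trp53 rose by 0.47 ± 0.12 (adjusted p = 0.0151). Among genes of at least 1 CPM, the largest falls on average were those of Ttc39a (-2.11 ± 0.51, adjusted p = 0.00898), the glycogen regulator Ppp1r3c (-1.903 ± 0.25, adjusted p = 1.05e-05) and the thromboxane receptor gene Tbxa2r (-1.69 ± 0.53, adjusted p = 0.0454). Ttc39a had 0 reads at 8 h and Tbxa2r 3 reads at 3 h, so their fitted folds rest on few reads.

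By list, 51 of 62 measured NF-kB targets rose on average (57 adjusted over the list alone), with a median of 1.81 and a camera adjusted p of 1.88e-76. Of 27 genes of NF-kB feedback and signalling 20 rose (23 adjusted over the list alone, median 1.52), among them Nfkb2 (1.52 ± 0.09), Birc3 (2.04 ± 0.13) and Nfkbie (3.43 ± 0.24). Of 21 chemokine genes 14 rose (15, with 1 lower, adjusted over the list alone, median 2.51), including Cxcl10 (3.40 ± 0.19) and Cx3cl1 (2.24 ± 0.18). Of 26 cytokine and growth factor genes 13 rose on both counts (median 1.12), and of 18 adhesion and complement genes 9 on both counts (median 0.557). Of 41 immediate early genes, transcription factors and feedback genes that respond within minutes, 30 rose (33 adjusted over the list alone, median 1.08), with Junb at 2.56 ± 0.18 and Zfp36 at 2.90 ± 0.27. Of 47 interferon response genes 24 rose (29 adjusted over the list alone, median 0.624), such as Gbp2 (1.87 ± 0.23) and Ifit2 (1.04 ± 0.15). The camera adjusted p was 8.83e-20, with an adjusted p = 0.0785 with an estimated correlation. Of 21 MHC class I presentation genes 9 rose (17 adjusted over the list alone, blocked 20, median 0.877), among them Tapbp (0.73 ± 0.10) and Psme2 (0.57 ± 0.07). Matrix proteases and inhibitors (9 of 23 rose, 11 up and 2 down adjusted over the list alone, blocked 13 and 3, median 0.711) included Serpina3g (1.54 ± 0.12). Survival and redox genes followed with 10 of 21 (11 adjusted over the list alone, blocked 14 up and 1 down, median 0.304), such as Sod2 (1.36 ± 0.15) and Gadd45b (2.01 ± 0.20).

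In these p53-less cells, 5 of 23 p53 targets rose and 2 fell, the same adjusted over the list alone (blocked 9 and 4, median 0.0894, camera adjusted p 0.0309), among them Fas (2.55 ± 0.21), Btg2 (2.59 ± 0.31) and Cdkn1a (1.45 ± 0.25). The cell cycle list had a median of -0.261 with 1 of 40 genes lower, Ccnb2 (-0.40 ± 0.13), none adjusted over the list alone and 13 lower in the blocked fit. Its camera adjusted p was 0.00358, with an adjusted p = 0.619 with an estimated correlation. Of 25 glycolysis and hypoxia genes 4 rose on both counts (blocked 6 and 1 lower), including the hexokinase gene Hk2 (1.28 ± 0.18), with a camera adjusted p of 0.114. None of 24 cholesterol synthesis genes passed on either count (blocked 1, median -0.0146, camera adjusted p 0.727). In the unfolded protein response list Hspa5 rose (0.40 ± 0.08) and Trib3 fell (-0.41 ± 0.09), out of 20 and the same adjusted over the list alone (blocked 3 and 1, camera adjusted p 0.266). None of 37 fibroblast matrix and identity genes passed on either count (blocked 4, camera adjusted p 0.319). No list of other cell types passed: macrophage (0 of 3, camera adjusted p 0.362), endothelial (1 of 3, Flt1, 0.22), epithelial (0 of 4, 0.736), muscle (0 of 3, 0.482) and neural markers (1 of 7 lower, Map2, 0.22). These counts were the same adjusted over the list alone, and the endothelial median (-0.0125) was opposite in sign to its mean (0.623) and its test.

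In the edgeR test 4264 of 13665 genes (31.2%) changed at some time in RelA-WT (blocked 7458), 2520 with a higher and 1744 with a lower mean. Without replicate 1 of RelA-WT that number was 1674, and without replicate 2 it was 2315. At 0.5 h 106 genes rose and 5 fell (blocked 154 and 24), and at 1 h 348 and 95 (614 and 315). These numbers were 1441 and 785 at 3 h (2303 and 1924) and 2161 and 1582 at 8 h (3155 and 2971). On average 855 rose and 330 fell (blocked 1731 and 1395).

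**Figure D2:**
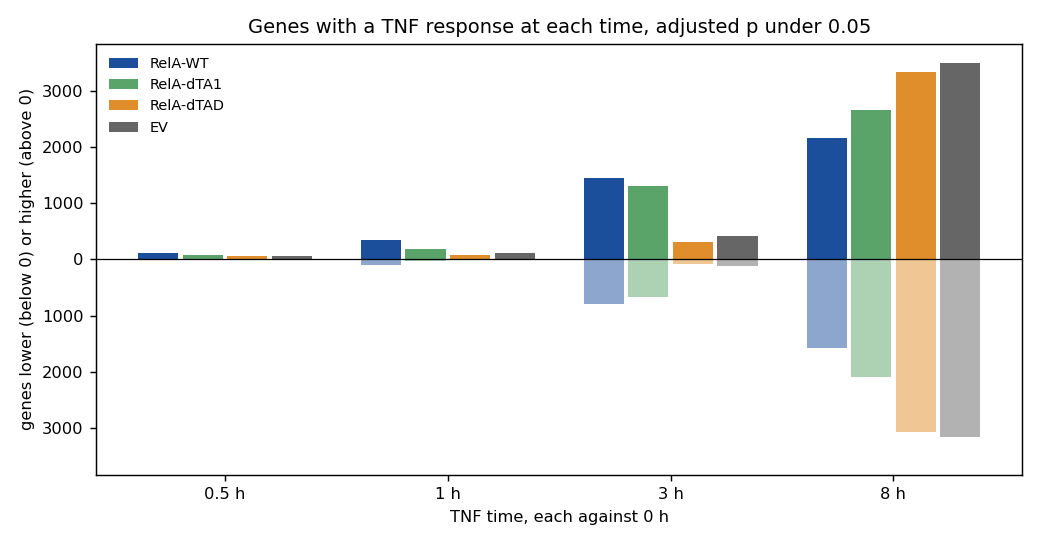
Number of genes higher (bars above 0) and lower (bars below 0) than at 0 h, at an adjusted p under 0.05, for each TNF time in RelA-WT, RelA-dTA1, RelA-dTAD and EV. At 1 h RelA-WT had 348 higher genes and EV 105, and at 8 h RelA-WT had 2161 and EV 3495.

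The course in EV cells shows the change after TNF without RelA. Egr1, a zinc finger transcription factor, was at 1218 ± 120.1 at 0.5 h in EV and 1219 ± 143 in RelA-WT, and Fos rose by 5.00 ± 0.30 at 0.5 h (adjusted p = 1.98e-10). Atf3, a stress transcription factor gene, rose on average by 3.39 ± 0.34 (adjusted p = 2.76e-07) and the orphan receptor gene Nr4a1 by 3.23 ± 0.31 (adjusted p = 1.73e-07). The antiproliferative gene Btg2 rose by 3.17 ± 0.32 and Egr4 by 3.45 ± 0.63. In contrast, Nfkbia went only from 28.1 ± 2.14 to 30.9 ± 0.870 at 1 h and 86.6 ± 3.90 at 8 h (average 0.61 ± 0.12, adjusted p = 0.00130). Vcam1 went from 118 ± 17.4 to 123 ± 14.6 at 3 h (average 0.18 ± 0.13, adjusted p = 0.417). Tnfaip3 (0.70 ± 0.31, adjusted p = 0.148), Icam1 (0.81 ± 0.75, adjusted p = 0.547), Birc3 (0.20 ± 0.12, adjusted p = 0.320) and Irf1 (-0.21 ± 0.12, adjusted p = 0.310) did not pass on average. Irf1 was lower at 8 h (-1.09 ± 0.17, adjusted p = 1.09e-05).

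At 8 h the highest EV responses included those in the gap junction gene Gjb2 (6.64 ± 0.77, adjusted p = 1.48e-07) and in the growth factor and cytokine genes Areg (6.21 ± 0.57) and Lif (5.52 ± 0.33). Nppb, the natriuretic peptide gene, had 193 reads at 8 h against 1 (ratio 281, 95% interval 49.9 to 11200) and Serpinb2 118 against 2 (ratio 85.9, 95% interval 23.3 to 718). The cell death gene Bmf fell by 8 h (-5.08 ± 0.57, adjusted p = 9.04e-08), as did the Toll-like receptor modulator Tril (-5.11 ± 0.73, adjusted p = 3.37e-06). Some NF-kB genes did rise on average in EV, among them Nfkb2 (0.58 ± 0.08), Cxcl10 (1.47 ± 0.17), Ccl2 (2.33 ± 0.41) and Ptgs2 (2.49 ± 0.16), the prostaglandin synthase gene. Ccl20 had 56 reads at 8 h against 2 (ratio 40.8, 95% interval 10.8 to 345). Among immediate early genes 39 of 41 rose on average (40 adjusted over the list alone, median 1.98). Of NF-kB targets 21 of 62 rose (22 up and 1 down adjusted over the list alone), with a median of 0.442, or 0.386 with genes of very few reads at their bound. Their camera adjusted p was 1.24e-09 but the adjusted p = 0.0897 with an estimated correlation. Of cytokine and growth factor genes 9 of 26 rose (10 adjusted over the list alone, median 0.776, or 0.55 at the bound), including Hbegf (2.08 ± 0.17) and Ereg (2.202 ± 0.25). Of chemokine genes 5 of 21 rose on both counts, a list that passed only with the preset correlation (adjusted p = 0.235 with an estimated correlation). One interferon response gene, Irgm1, rose (0.53 ± 0.13), and no MHC class I gene did. At 0.5 h 55 genes rose and none fell in EV (blocked 96 and 11), and at 1 h 105 and 8 (235 and 63). These numbers were 412 and 126 at 3 h (1261 and 957) and 3495 and 3157 at 8 h (4356 and 4200). At some time 5836 genes (42.7%) changed, with 3213 means higher and 2623 lower, against 3104 without EV replicate 1 and 3436 without replicate 2.

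The courses of RelA-dTA1 and RelA-dTAD show the change after TNF when RelA lacks TA1 or the whole transactivation region. In RelA-dTA1 Nfkbia reached 444 ± 93.6 at 1 h and rose on average by 2.94 ± 0.14 (adjusted p = 4.18e-13). Irf1 rose by 2.49 ± 0.14, Vcam1 by 1.89 ± 0.15, Cxcl10 by 3.01 ± 0.18 and Ccl20 by 4.70 ± 0.41. Of NF-kB targets 49 of 62 rose (53 adjusted over the list alone, median 1.53, adjusted p = 7.04e-06 with an estimated correlation). Interferon response genes rose in 21 of 47 cases (26 adjusted over the list alone, median 0.576, adjusted p = 0.152 with an estimated correlation). In RelA-dTAD Nfkbia was at 48.6 ± 1.901 at 1 h, with an average rise of 0.88 ± 0.12 (adjusted p = 3.21e-05). Vcam1 rose by 0.60 ± 0.14 (adjusted p = 0.00441) and Tnfaip3 by 1.395 ± 0.29 (adjusted p = 0.00267). Irf1 (0.27 ± 0.12, adjusted p = 0.183), Ccl5 (0.19 ± 0.17, adjusted p = 0.534) and Icam1 (0.92 ± 0.63, adjusted p = 0.407) did not pass there. Of NF-kB targets 23 of 62 rose in RelA-dTAD (31 adjusted over the list alone, median 0.646, or 0.545 at the bound, adjusted p = 0.00974 with an estimated correlation). Of immediate early genes 37 of 41 rose (41 adjusted over the list alone), such as Fos (2.46 ± 0.26) and Egr1 (1.77 ± 0.30), and none of 47 interferon response genes (blocked 3). RelA-dTA1 had 84 genes up and 2 down at 0.5 h (blocked 139 and 22), 192 and 29 at 1 h (450 and 189), 1309 and 665 at 3 h (2336 and 1836) and 2648 and 2086 at 8 h (3629 and 3505). RelA-dTAD had 60 and 0 at 0.5 h (blocked 114 and 13), 73 and 2 at 1 h (216 and 43), 311 and 86 at 3 h (1009 and 692) and 3333 and 3075 at 8 h (4349 and 4321). At some time 4494 genes (32.9%, blocked 7876) changed in RelA-dTA1 and 5385 (39.4%, blocked 8430) in RelA-dTAD. Without replicate 1 or 2 of the construct itself these were 1720 or 2413 in RelA-dTA1 and 2944 or 3223 in RelA-dTAD.

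The difference between the EV and RelA-WT responses asks which TNF responses needed RelA. Nfkbia and Irf1 lost most of their response in EV, with differences of -3.04 ± 0.17 (adjusted p = 1.43e-11) and -3.44 ± 0.18 (adjusted p = 1.10e-11). So did Vcam1 (-2.48 ± 0.19, adjusted p = 1.02e-08) and Tnfaip3 (-3.78 ± 0.42, adjusted p = 8.21e-06). Gbp5, an interferon-induced GTPase gene, went from 3.49 ± 0.265 to 269.8 ± 25.1 CPM at 3 h in RelA-WT and from 0.937 ± 0.151 to 1.23 ± 0.0359 in EV (-4.47 ± 0.89, adjusted p = 0.00642). Cxcl9 was at 209.6 ± 26.3 at 8 h in RelA-WT and 0.856 ± 0.479 in EV (-5.66 ± 0.71, adjusted p = 3.26e-05, with 1 read at 1 h in EV). In the other direction Hbegf, a growth factor gene (chr18:36504929-36515805), reached 616 ± 19.9 at 8 h in EV and 36.1 ± 1.401 in RelA-WT, an average difference of 1.73 ± 0.22 (adjusted p = 4.19e-05). Dusp4, which encodes a MAP kinase phosphatase, differed by 1.74 ± 0.34 (adjusted p = 0.00621).

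**Figure D3:**
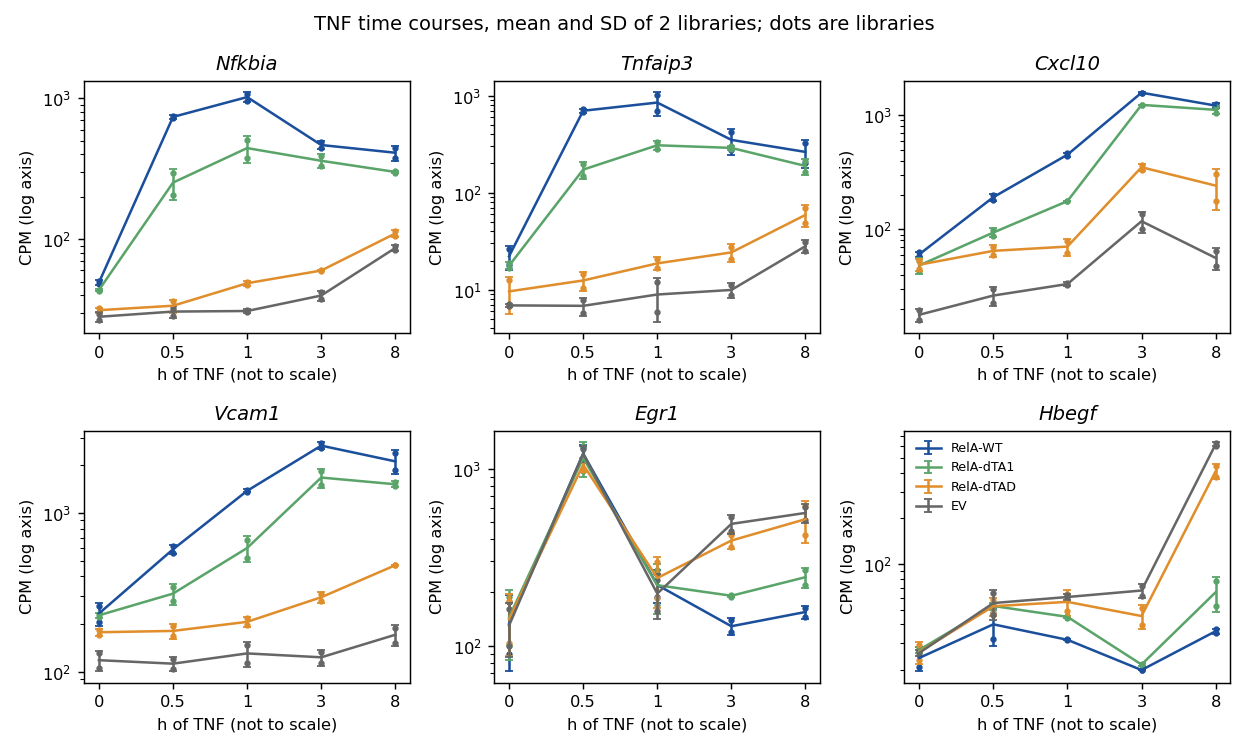
Levels in CPM (log axis) of Nfkbia, Tnfaip3, Cxcl10, Vcam1, Egr1 and Hbegf against time after TNF in RelA-WT, RelA-dTA1, RelA-dTAD and EV, as means with SD (n = 2) and a dot per library. Nfkbia at 1 h stood at 1022 ± 79.7 in RelA-WT, 444 ± 93.6 in RelA-dTA1, 48.6 ± 1.901 in RelA-dTAD and 30.9 ± 0.870 in EV.

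Of 62 NF-kB targets 24 responded less in EV than in RelA-WT and 1 more (34 and 1 adjusted over the list alone, blocked 34 and 1). Their median difference was -1.21, or -1.31 with 7 genes of very few reads at their bound, with a camera adjusted p of 4.06e-62. Of 27 feedback and signalling genes 12 responded less (15 adjusted over the list alone), such as Birc3 (-1.84 ± 0.17), Tnip1 (-1.47 ± 0.15) and Nfkb2 (-0.94 ± 0.11). Of 21 chemokine genes 5 responded less (9 adjusted over the list alone, median -1.78), including Ccl5 (-2.14 ± 0.25), Cxcl10 (-1.94 ± 0.23) and Cx3cl1 (-1.66 ± 0.23). Ccl2 (-1.50 ± 0.51, adjusted p = 0.193, blocked 0.0418) and Ccl20 (adjusted p = 0.612) did not pass on average over the times. By reads, Ccl20 in EV was 413-fold below RelA-WT at 0.5 h (3 against 1057, 95% interval 141 to 2010) and 246-fold at 3 h (3 against 627, 95% interval 83.7 to 1200), against 17.8-fold before TNF (2 against 34, 95% interval 4.57 to 153). At 1 h EV had 1 read against 1767, with an interval of 311 to 68500, and at 8 h 56 against 2058. Of 18 adhesion and complement genes 3 responded less (5 adjusted over the list alone, blocked 5), among them Sele (-3.72 ± 0.78, adjusted p = 0.00926). Icam1 did not pass (-3.38 ± 1.01, adjusted p = 0.108, blocked 0.0102). Of 47 interferon response genes 9 responded less (16 adjusted over the list alone, blocked 14, median -0.573), with a camera adjusted p of 4.74e-19 and an adjusted p = 0.103 with an estimated correlation. Of 21 MHC class I genes 5 responded less (10 adjusted over the list alone, blocked 11), such as Tapbpl (-1.26 ± 0.18) and Psmb10 (-1.19 ± 0.23). Of 21 survival and redox genes 7 responded less and 1 more (8 and 2 adjusted over the list alone), including the death receptor gene Fas (-2.56 ± 0.31) and Sod2 (-1.14 ± 0.20). On average over the times, immediate early genes responded more in EV, 5 of 41 with 1 lower (19 and 4 adjusted over the list alone, blocked 12 and 4, median 0.561, adjusted p = 0.0215 with an estimated correlation). They included Dusp6 (1.21 ± 0.18), Klf4 (0.91 ± 0.21) and Egr3 (1.08 ± 0.25), against Gadd45b (-1.82 ± 0.26). This came from the later times. At 0.5 and 1 h 2 and 6 of the 41 genes responded less and none more (medians 0.0241 and -0.133, adjusted p = 0.15 and 0.0938 with an estimated correlation). At 3 h 11 responded more and 2 less, and at 8 h 26 more and none less (medians 0.847 and 1.52, adjusted p = 0.00391 and 0.00503 with an estimated correlation). Adjusted over the list alone these were 0 and 4, 1 and 7, 20 and 3, and 31 and 0 (blocked 0 and 3, 1 and 7, 21 and 2, and 35 and 0). Of 26 cytokine and growth factor genes 1 responded more and 3 less (3 and 3 adjusted over the list alone, blocked 4 and 4). The list passed only with the preset correlation (adjusted p = 0.081 with an estimated correlation).

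On average over the times 63 genes responded more and 179 less in EV than in RelA-WT (blocked 332 and 501). Their total of 242 was 79 or 77 without RelA-WT replicate 1 or 2, and 83 or 59 without EV replicate 1 or 2. By time these numbers were 0 and 11 at 0.5 h (blocked 0 and 20), 3 and 79 at 1 h (25 and 173), 120 and 383 at 3 h (450 and 789) and 1321 and 1079 at 8 h (2501 and 2072). At 0.5 h the lower genes included Nfkbia (-3.79 ± 0.21) and Irf1 (-3.09 ± 0.22), and Sele (-4.87 ± 0.87, adjusted p = 0.0126) was not kept in the blocked fit (adjusted p = 0.0875). At 3 h Fos (2.46 ± 0.44) and Nr4a1 (2.88 ± 0.50) responded more in EV, and at 8 h Areg (6.18 ± 0.92) and the semaphorin gene Sema7a (5.04 ± 0.71). Without the 8 h libraries, a choice made after seeing the data, 5 genes responded more and 82 less (blocked 43 and 226).

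Removing the transactivation domains asks how much of the response they carry, against RelA-WT and against EV. Against RelA-WT, RelA-dTAD fell short at Nfkbia (-2.78 ± 0.17, adjusted p = 8.90e-11), Irf1 (-2.97 ± 0.18, adjusted p = 8.90e-11), Vcam1 (-2.06 ± 0.19, adjusted p = 3.60e-07) and Tnfaip3 (-3.08 ± 0.39, adjusted p = 4.75e-05). Cxcl9 reached 41.9 ± 1.52 at 8 h (-3.54 ± 0.37, adjusted p = 2.67e-06), and Icosl, a T cell costimulator gene, differed by -3.99 ± 0.82 (adjusted p = 0.0131). Hbegf (1.35 ± 0.22, adjusted p = 0.00137), Dusp4 (1.36 ± 0.34, adjusted p = 0.0492) and Tnfrsf12a, the TWEAK receptor gene (1.09 ± 0.20, adjusted p = 0.00527), responded more. Of NF-kB targets 21 of 62 responded less (36 lower and 2 higher adjusted over the list alone), with a median of -1.11, or -1.25 with 5 genes at their bound. Feedback and signalling genes responded less in 11 of 27 cases (17 adjusted over the list alone), with Tnip1 at -1.54 ± 0.14 and Birc3 at -1.51 ± 0.16. Chemokine genes did so in 5 of 21 cases (11 adjusted over the list alone, blocked 8), with Cxcl10 at -1.88 ± 0.22 and Ccl5 at -1.75 ± 0.23. Of interferon response genes 4 of 47 responded less (16 adjusted over the list alone, blocked 14), a list with an adjusted p = 0.0917 with an estimated correlation. MHC class I genes responded less in 3 of 21 cases (7 adjusted over the list alone, blocked 11), survival and redox genes in 7 of 21 (9 lower and 3 higher adjusted over the list alone). In all, 26 genes responded more and 117 less (blocked 206 and 429). By time these numbers were 0 and 11 at 0.5 h (blocked 1 and 27), 0 and 82 at 1 h (30 and 195), 82 and 341 at 3 h (384 and 756) and 881 and 792 at 8 h (2030 and 1768). Without the 8 h libraries 1 responded more and 67 less (blocked 29 and 230). The total of 143 was 39 or 44 without RelA-WT replicate 1 or 2, and 33 or 28 without RelA-dTAD replicate 1 or 2.

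Against EV no difference in the average response of RelA-dTAD passed the edgeR test, with 107 genes at an unadjusted p under 0.05, 0 by DESeq2 and 0 blocked. The median difference was 0.104 for NF-kB targets, with a camera adjusted p of 0.000495 and an adjusted p = 0.388 with an estimated correlation. At 0.5, 1 and 3 h no gene passed in edgeR, with 92, 114 and 113 genes at an unadjusted p under 0.05, and 0, 4 and 0 were higher in the blocked fit. At 8 h the arginine transporter gene Slc7a2 responded more in RelA-dTAD (1.96 ± 0.30, adjusted p = 0.0127), at 236 ± 79.4 CPM against 47.9 ± 7.24 in EV, the only gene to pass (blocked 7 and 6). These few differences do not show that the 2 constructs act alike.

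Loss of TA1 alone was compared with RelA-WT to see what TA1 adds. At 0.5 h Nfkbia (-1.37 ± 0.20, adjusted p = 0.00546) and Irf1 (-1.30 ± 0.22, adjusted p = 0.0211) responded less in RelA-dTA1, with Nfkbia at 252 ± 63.6 CPM against 739 ± 23.5. No other gene passed (blocked 4 higher and 6 lower). On average no gene passed in edgeR, with 134 at an unadjusted p under 0.05, 0 by DESeq2, 4 higher in the blocked fit and 1 without RelA-dTA1 replicate 2. Vcam1 (-0.78 ± 0.18), Irf1 (-0.75 ± 0.17) and Nfkbia (-0.72 ± 0.16) had the adjusted p = 1 of nearly all genes. Taken as a list, NF-kB targets were lower by a median of -0.309 (0 of 62 passed, 4 adjusted over the list alone). The camera adjusted p was 7.39e-22, with an adjusted p = 0.00372 with an estimated correlation. Chemokine (-0.401) and feedback genes (-0.213) were lower too, both with an adjusted p = 0.00372 with an estimated correlation. At 1, 3 and 8 h no gene passed in edgeR, with 219, 182 and 265 genes at an unadjusted p under 0.05. The blocked fit gave 4 higher and 27 lower, 3 and 3, and 4 and 4.

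Against RelA-dTAD, which lacks more, RelA-dTA1 responded more at Irf1 (2.22 ± 0.18, adjusted p = 3.53e-08), Nfkbia (2.06 ± 0.16, adjusted p = 3.53e-08), Cxcl9 (2.89 ± 0.36, adjusted p = 1.22e-04) and Vcam1 (1.28 ± 0.18, adjusted p = 6.17e-04). It responded less at Hbegf (-1.05 ± 0.22, adjusted p = 0.0317) and Dusp6 (-0.85 ± 0.18, adjusted p = 0.0373). Of 62 NF-kB targets 12 responded more (27, with 1 lower, adjusted over the list alone, blocked 23), with a median of 0.793. Of 27 feedback genes 7 did (12 adjusted over the list alone, blocked 13), such as Tnip1 (1.18 ± 0.14) and Birc3 (1.17 ± 0.16). Of 21 chemokine genes 4 responded more (8 adjusted over the list alone). Of interferon response genes 1 of 47 did, Irf1 (10 adjusted over the list alone, blocked 5, adjusted p = 0.107 with an estimated correlation). In all, 31 genes responded more and 3 less (blocked 174 and 41), with 14 or 8 in total without RelA-dTA1 replicate 1 or 2 and 9 or 12 without RelA-dTAD replicate 1 or 2. They were 16 and 0 without the 8 h libraries (blocked 56 and 1). By time the numbers were 3 and 0 at 0.5 h (blocked 10 and 0), 13 and 0 at 1 h (49 and 2), 184 and 16 at 3 h (512 and 162) and 428 and 384 at 8 h (1306 and 1391).

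Levels before TNF were compared to see what RelA does in resting cells. C3, the central complement gene (chr17:57203970-57228136), stood at 29.3 ± 8.75 CPM in RelA-WT, 28.6 ± 0.347 in RelA-dTA1, 0.644 ± 0.396 in RelA-dTAD and 0.317 ± 0.334 in EV (-6.76 ± 0.46 against RelA-WT, adjusted p = 1.68e-09). The acute phase gene Saa3 had 891 reads in RelA-WT and 1 in EV, which is 934-fold lower (95% interval 167 to 36900). The chemokine genes Ccl2 (-3.63 ± 0.46, adjusted p = 9.73e-05) and Cxcl10 (-1.77 ± 0.20, adjusted p = 2.11e-05) and the matrix protease genes Mmp3 (-2.39 ± 0.34, adjusted p = 4.74e-04) and Mmp13 (-3.39 ± 0.71, adjusted p = 0.0163) were lower in EV. So were Hp, which encodes the hemoglobin binder haptoglobin (-3.94 ± 0.78), Vcam1 (-0.99 ± 0.17) and Nfkbia (-0.82 ± 0.15). Tnip3, an A20-binding protein gene, had 0 reads in EV and 16 in RelA-WT, at least 5.59-fold lower.

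Interferon response genes made up the largest group, with 23 of 47 lower in EV (44 adjusted over the list alone, blocked 32). Their median was -1.19, with a camera adjusted p of 1.52e-109 and an adjusted p = 0.000351 with an estimated correlation. They included Oas1a (-2.51 ± 0.36) and Parp14 (-1.52 ± 0.24). Of 62 NF-kB targets 13 were lower (17 adjusted over the list alone), with a median of -0.443, or -0.415 with 4 genes at their bound. Of MHC class I genes 2 of 21 were lower (16 adjusted over the list alone, blocked 14), Tapbp (-0.64 ± 0.12) and H2-T22 (-0.65 ± 0.14). Chemokine genes were lower in 4 of 21 cases (6 adjusted over the list alone, median -1.17, or -0.72 at the bound) and matrix proteases and inhibitors in 3 of 23 on both counts. Adhesion and complement genes were lower in 3 of 18 cases on both counts and feedback genes in 3 of 27 (4 adjusted over the list alone). In all, 77 genes were lower and none higher in EV (blocked 147 and 8, DESeq2 102 in all). That number was 24 or 44 without RelA-WT replicate 1 or 2, and 16 without EV replicate 1.

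RelA-dTAD kept its interferon response genes before TNF, with a median of 0.174 against RelA-WT and 0 of 47 passing on either count (camera adjusted p 1.88e-06, adjusted p = 0.42 with an estimated correlation). Against EV, a comparison added after seeing the data, 32 of these 47 genes were higher in RelA-dTAD (44 adjusted over the list alone, median 1.33) and 23 in RelA-dTA1 (43 adjusted over the list alone, blocked 35, median 1.19). In all, 87 genes were higher and 1 lower in RelA-dTAD than in EV (blocked 162 and 8), and 81 and 0 in RelA-dTA1 (blocked 172 and 6). Against RelA-WT 4 genes were lower in RelA-dTAD (blocked 2 higher and 7 lower, DESeq2 5, and 1 without RelA-dTAD replicate 2). They were C3 (-5.77 ± 0.40, adjusted p = 4.30e-09) and Saa3, with 4 reads in RelA-dTAD (-8.26 ± 0.85, adjusted p = 2.27e-05). The others were the protease inhibitor gene Spint2 (-2.36 ± 0.41, adjusted p = 0.0198) and the axon guidance gene Ntn1 (-1.38 ± 0.16, adjusted p = 5.15e-05). NF-kB targets had 2 of 62 lower (10 adjusted over the list alone, blocked 3, median -0.249, or -0.215 at the bound). No gene differed before TNF between RelA-dTA1 and RelA-WT in edgeR, with 154 genes at an unadjusted p under 0.05, 0 by DESeq2 and 4 lower in the blocked fit.

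The constructs with 1 library per time ask what single sites and domains contribute, and they have no replicate check. Before TNF, RelA-DB and RelA-dCterm had Rela at 57.3% and 46.2% of RelA-WT in set 1. By 8 h they stood at 1758 and 1728 CPM against 1483 in RelA-WT. A lower starting dose of RelA thus cannot be told apart from loss of the site or domain in these 2 constructs. In RelA-DB, whose DNA binding is mutated, the responses of Irf1 (-3.47 ± 0.22, adjusted p = 5.91e-10), Tnfaip3 (-3.47 ± 0.63, adjusted p = 0.00827), Nfkbie (-3.37 ± 0.51, adjusted p = 0.00136) and Tlr2, a bacterial pattern receptor gene (-3.65 ± 0.57, adjusted p = 0.00200), were below those in RelA-WT. Those of Hbegf (1.71 ± 0.28, adjusted p = 0.00355), Dusp4 (2.15 ± 0.45, adjusted p = 0.0247) and Tnfrsf12a (1.41 ± 0.26, adjusted p = 0.00827) were above. In RelA-dCterm, which is truncated at the C-terminus, Irf1 (-3.25 ± 0.22, adjusted p = 1.03e-09), Nfkbia (-3.07 ± 0.21, adjusted p = 1.03e-09) and Tlr2 (-3.59 ± 0.56, adjusted p = 0.00203) responded less and Hbegf more (1.60 ± 0.29, adjusted p = 0.00732). Nfkbie (-3.08 ± 0.55, adjusted p = 0.00667) was not kept in the blocked fit (adjusted p = 0.0564). Of 65 NF-kB targets 15 responded less in RelA-DB (28 lower and 1 higher adjusted over the list alone) and 17 in RelA-dCterm (24 lower and 1 higher adjusted over the list alone). The lists had adjusted p = 5.05e-05 and 3.53e-05 with an estimated correlation. In all, 18 genes responded more and 56 less in RelA-DB (blocked 142 and 249), and 10 and 48 in RelA-dCterm (blocked 87 and 191). Without RelA-WT replicate 1 or 2 the totals were 22 or 24 in RelA-DB and 29 or 17 in RelA-dCterm. Against EV neither construct had a gene past the edgeR test, blocked fit included, with 264 and 291 genes at an unadjusted p under 0.05, and DESeq2 was not run on these 75 libraries.

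With the CI change and without TA1, in RelA-TA2_CI-dTA1, Irf1 (-2.21 ± 0.20, adjusted p = 7.48e-07), Nfkbia (-2.09 ± 0.19, adjusted p = 6.91e-07), Tnfaip3 (-2.38 ± 0.44, adjusted p = 0.0262) and Cxcl9 (-2.44 ± 0.49, adjusted p = 0.0492) responded less than in RelA-WT. Errfi1, an inhibitor of growth factor receptors (1.15 ± 0.23, adjusted p = 0.0492), and Dusp6 (1.09 ± 0.22, adjusted p = 0.0492) responded more. RelA-TA2_CI_S467A-dTA1 was lower at Irf1 (-2.22 ± 0.20), Nfkbia (-2.02 ± 0.18), Tnfaip3 (-2.52 ± 0.42) and the small GTPase gene Rnd1 (-1.903 ± 0.30). Of 65 NF-kB targets 10 responded less in the first (25 lower and 1 higher adjusted over the list alone, blocked 17) and 11 in the other (23 adjusted over the list alone, blocked 21). In all, 2 genes responded more and 14 less in RelA-TA2_CI-dTA1 (blocked 40 and 105), and 0 and 12 in RelA-TA2_CI_S467A-dTA1 (blocked 25 and 86). Without RelA-WT replicate 1 or 2 the totals were 6 or 4 in the former and 3 or 2 in the latter. Against RelA-dTAD neither had a gene past the edgeR test, with 163 and 192 at an unadjusted p under 0.05 and 1 gene higher in the blocked fit of the latter. With TA1 intact, no gene passed in edgeR for RelA-TA2_CI, RelA-TA2_S467A or RelA-TA2_CI_S467A against RelA-WT, blocked fit included, with 186, 88 and 168 genes at an unadjusted p under 0.05. As a list, NF-kB targets had a median of -0.339 in RelA-TA2_CI (0 of 65 on either count, adjusted p = 0.00701 with an estimated correlation). It was 0.0927 in RelA-TA2_S467A (camera adjusted p 0.583) and -0.0921 in RelA-TA2_CI_S467A (7.05e-05, adjusted p = 0.34 with an estimated correlation).

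The list medians above for RelA-TA2_CI, RelA-TA2_S467A and RelA-TA2_CI_S467A are against RelA-WT of both sets, so they can differ from those here. In these libraries as they stand, the median difference in NF-kB target response from RelA-WT of the same set was -1.29 in RelA-DB, -1.04 in RelA-dCterm and -0.40 in RelA-TA2_CI. It was -0.217 in RelA-TA2_CI_S467A, -0.853 in RelA-TA2_CI-dTA1 and -0.907 in RelA-TA2_CI_S467A-dTA1. Of the 65 genes 57, 58, 57, 48, 56 and 57 were lower in these 6 constructs, and no random list of 10000 went as low. RelA-TA2_S467A differed by 0.0531, at the 99.8th percentile of random lists, with 27 genes lower. The sign turned with the way it is summarised, since its own median response was 1.74 against 1.9 in RelA-WT. Random lists were matched on expression only and not on response to TNF, so their range does not measure the spread between replicates. Between the sets of EV, RelA-dTAD and RelA-dTA1 the same median difference had a pooled SD of 0.0514, close to the 0.0531 of RelA-TA2_S467A. For comparison, EV differed by -1.22 in set 1 and -1.33 in set 2, RelA-dTAD by -1.14 and -1.17 and RelA-dTA1 by -0.294 and -0.353.

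**Figure D4:**
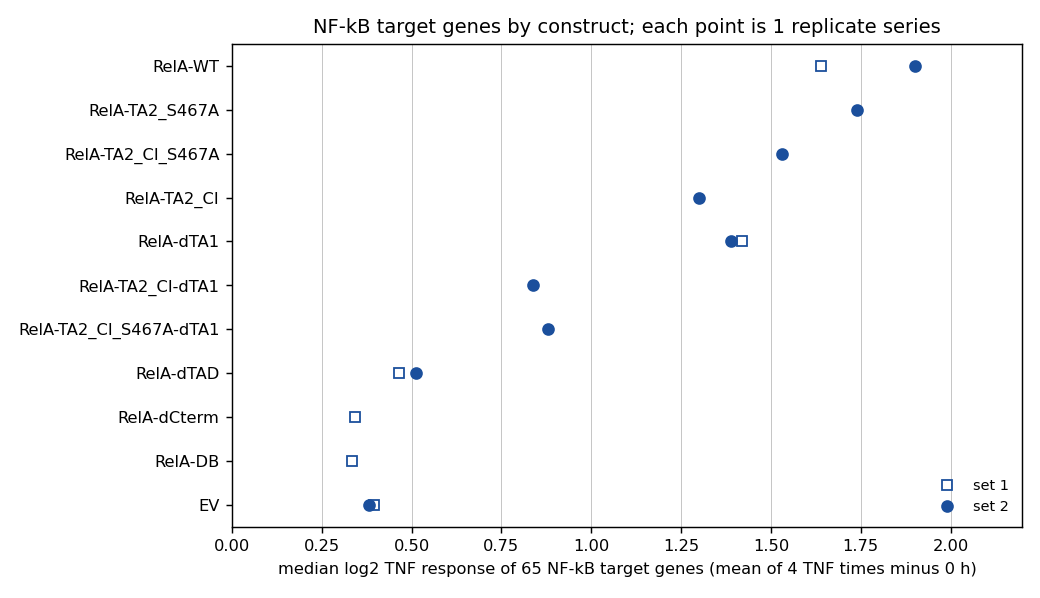
Median log2 response to TNF, averaged over 4 times, of 65 NF-kB target genes in each construct, with squares for set 1 and filled circles for set 2, 1 symbol per set. RelA-WT lies at 1.64 and 1.9 and EV at 0.395 and 0.382.

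Averaged over 3 backgrounds each, the dTA1 change lowered 12 genes and raised none (blocked 86 and 19, with 7 lower without RelA-dTA1 replicate 1 and 6 without RelA-WT replicate 2). Among them were Irf1 (-1.39 ± 0.13, adjusted p = 6.49e-07), Cxcl9 (-1.62 ± 0.31, adjusted p = 0.0365), Nfkbie (-1.37 ± 0.21, adjusted p = 0.00410) and Tnfaip3 (-1.37 ± 0.26, adjusted p = 0.0411). The CI change lowered Irf1 (-0.89 ± 0.13, adjusted p = 0.00199) and Nfkbia (-0.87 ± 0.11, adjusted p = 9.69e-04) and no other gene (blocked 28 lower and 4 higher). The S467A change moved no gene in edgeR, blocked fit included, with 199 genes at an unadjusted p under 0.05. Of 65 NF-kB targets the dTA1 change lowered 9 (23 lower and 1 higher adjusted over the list alone, blocked 19, median -0.493). The CI change lowered 2 (14 adjusted over the list alone, blocked 10, median -0.261) and the S467A change none (median 0.0682, adjusted p = 0.457 with an estimated correlation). By background in set 2, the CI change shifted the list median by -0.40 next to RelA-WT, by -0.155 with S467A and by -0.425 without TA1. Loss of TA1 shifted it by -0.353 next to RelA-WT, by -0.427 with CI and by -0.667 with CI and S467A, and S467A by 0.0531, by 0.188 with CI and by -0.0112 with CI and without TA1.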

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

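The comparisons of average TNF responses and of unstimulated levels with RelA-WT, that of RelA-dTA1 with RelA-dTAD, the list tests, and the sequencing depth and RNA length tests were planned before their results were seen. Differences between constructs at single times were not among the planned tests. The random lists for the interferon genes, the relations of list medians and Rela levels across constructs, the tests on Rela and the use of a list test against drift were chosen after the pattern they address was seen. Repeating the depth test over 5 draws, and using the lowest, was decided after the value of the opening draw was known.

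The TNF response differed between constructs in direct tests of the difference in edgeR, which singled out these comparisons. Averaged over the TNF times, 242 genes differed between EV and RelA-WT (63 more, 179 less in EV), 143 between RelA-dTAD and RelA-WT (26 and 117) and 34 between RelA-dTA1 and RelA-dTAD (31 and 3). In the constructs with 1 library per time, 74 genes differed from RelA-WT in RelA-DB (18 and 56), 58 in RelA-dCterm (10 and 48), 16 in RelA-TA2_CI-dTA1 (2 and 14) and 12 in RelA-TA2_CI_S467A-dTA1 (0 and 12). Averaged over backgrounds, 2 genes responded less with the CI change and 12 with the dTA1 change. Those numbers from lone libraries have no replicate check of their own.

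Interferon response genes were lower before TNF in EV than in RelA-WT, with a list median of -1.19, while RelA-dTAD had them at 0.174. By set, EV lay at -1.56 in set 1 and -0.867 in set 2. Random lists of equal size and expression reached only -0.0567 at their lower bound. Library scaling holds the median of all genes near 0 (-0.0135), so these lists cannot test a scaling error. They show only that the interferon genes were lower relative to genes of like expression. Drift of the list between lines cannot be told apart from an effect of RelA, since the list's adjusted p of 0.000351 with an estimated correlation covers only the spread between these libraries, whose cultures may not be separate. RelA-dTAD had Rela at 97.6% and 121.9% of RelA-WT in sets 1 and 2, with interferon medians of 0.164 and 0.176. Loss of the transactivation domains at such Rela levels thus came without lower interferon genes in its libraries. For RelA-DB and RelA-dCterm, a lower dose of the introduced RelA cannot be told apart from a loss of its function. They had interferon medians of -1.52 and -0.99 against RelA-WT of their set, with Rela levels of at most 57.3% of it. RelA-dTA1 in set 1 was at 0.0066 with Rela at 73.7%. The 5 TA2 mutants, all in set 2, were at -0.211 to -0.459 with Rela at 78.1% to 97.9%, beside -0.867 in EV of that set. Lone lines with much Rela thus lay below RelA-WT as well, and that RelA keeps these genes on stays an open hypothesis.

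The Rela transcript rose more by 8 h in RelA-dTAD than in RelA-WT, by a log2 of 1.56, although the same vector carries both. The median of all genes differed by 0.00949. Library scaling holds this median near 0, so it cannot test a scaling error, and it shows only that Rela rose relative to most genes. Reads of the chromosomal gene are argued against by EV, where Rela rose by 0.304% of the CPM rise in RelA-dTAD. Over 10 RelA constructs, the 8 h change of Rela followed the 8 h median of the immediate early genes (r = 0.951, permutation p = 0.00031, adjusted 0.00062; rho = 0.867, p = 0.00202, adjusted 0.00323, in a family of 2 relations). Without the 2 constructs farthest from the median r was 0.925, and in the 8 constructs of set 2 it was 0.956 (permutation p = 0.0011; rho = 0.881, p = 0.00716). A vector driven by the same signals as the immediate early genes is consistent with these values, as a hypothesis drawn from the same data.

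The 8 h response was broader in EV than in RelA-WT, with 2400 genes that differed and higher immediate early genes. With the 40 libraries of the replicated constructs thinned to 4663288 reads each, 1256 to 1347 genes still differed over 5 draws, and EV had 4886 to 4985 changed genes against 2304 to 2375 in RelA-WT at equal depth, so depth alone is argued against, though the lowest draw passed the planned bound only narrowly. The longest genes changed in EV by 0.0924 more than the shortest, where RNA degradation would give less. That gap passed the planned bound only narrowly. A true response of long genes could offset a loss, so this test does not exclude degradation. Over 11 constructs the 8 h immediate early median fell as the NF-kB median rose (r = -0.787, permutation p = 0.00792, adjusted 0.00792; rho = -0.818, p = 0.00323, adjusted 0.00323), and r was -0.708 without the 2 constructs farthest from the median. In the 9 constructs of set 2 r was -0.777 (permutation p = 0.00294, with rho = -0.75 and p = 0.026) and -0.516 without its 2 farthest. Some lone lines broke the relation. RelA-TA2_CI-dTA1 and RelA-TA2_CI_S467A-dTA1 had NF-kB medians of 1.979 and 1.886 at 8 h, near the 2.161 of RelA-WT in set 2. Their immediate early medians were 1.925 and 2.032 against 0.6728. RelA-TA2_CI_S467A was above RelA-WT in both, at 2.558 and 1.152. Restraint of late signalling by RelA transactivation thus stays a hypothesis only.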

How the results depend on the processing

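Chosen after seeing the data were leaving out the 8 h times, all alternative settings of the 12 comparisons of lone-library constructs, and the left-out replicates for the 3 averaged changes. With DESeq2 size factors 27 of 27 counts of genes stayed within 1.5 times, and with DESeq2 12 of 12. No count above 0 went to 0 in any setting run except that of the CI change under the 2-fold minimum. Where no reason is given with a value, the cause was not tested.

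With the replicate block 10 of 27 counts stayed within 1.5 times and 17 rose, beside a lower dispersion. Genes changed at some time were 7458 in RelA-WT, 7876 in RelA-dTA1 and 8430 in RelA-dTAD. Differences in response were 833 for EV against RelA-WT, 635 for RelA-dTAD, 4 for RelA-dTA1 and 215 for RelA-dTA1 against RelA-dTAD, and before TNF 155, 9 and 4 for EV, RelA-dTAD and RelA-dTA1. They were 391 for RelA-DB, 278 for RelA-dCterm, 145 for RelA-TA2_CI-dTA1, 111 for RelA-TA2_CI_S467A-dTA1 (1 against RelA-dTAD), 32 for the CI and 105 for the dTA1 change. Of 354 named gene values 351 kept their call with the block, and Sele at 0.5 h in EV, Ccl20 at 1 h in RelA-dTAD and Nfkbie in RelA-dCterm lost it. Calls were lost for 6 of the 354 with other size factors, 23 with no filter, 7 of 295 with DESeq2 and 595 of 2676 with a replicate left out, and none turned its direction.

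A minimum of 2-fold, which by construction lowers counts, gave 1357 genes in RelA-WT, 2373 in EV, 1469 in RelA-dTA1 and 2114 in RelA-dTAD. It gave 95 for EV against RelA-WT, 63 for RelA-dTAD, 19 for RelA-dTA1 against RelA-dTAD, 49 for EV before TNF, 41 for RelA-DB, 36 for RelA-dCterm, 0 for the CI and 7 for the dTA1 change. A test for a difference at any time, which also takes in genes that differ at single times, gave 2273 for EV, 1704 for RelA-dTAD and 10 for RelA-dTA1 against RelA-WT, 1 for RelA-dTAD against EV and 869 for RelA-dTA1 against RelA-dTAD.

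With no filter on low counts (27388 genes in the 40 libraries), 410 genes differed for EV, 303 for RelA-dTAD and 21 for RelA-dTA1 against RelA-WT and 127 for RelA-dTA1 against RelA-dTAD. Before TNF there were 162, 24 and 7 for EV, RelA-dTAD and RelA-dTA1. The lone-library constructs had 200 (RelA-DB), 199 (RelA-dCterm), 9 (RelA-TA2_CI), 77 (RelA-TA2_CI-dTA1) and 74 (RelA-TA2_CI_S467A-dTA1), and the averaged changes 32 (CI), 2 (S467A) and 83 (dTA1). There were 5 for RelA-dCterm against EV, and 6 for RelA-TA2_CI-dTA1 and 2 for RelA-TA2_CI_S467A-dTA1 against RelA-dTAD. Without the 8 h times 87 genes differed for EV, 68 for RelA-dTAD and 16 for RelA-dTA1 against RelA-dTAD.

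Leaving out replicates lowered 34 of 156 counts by more than 1.5 times and raised 1. A construct left with 1 library per time was assumed to vary like the other groups. Genes changed at some time ran from 1674 to 4129 in RelA-WT (1674 without its replicate 1, 2315 without 2), 3104 to 5753 in EV (3104, 3436), 1720 to 4370 in RelA-dTA1 (1720, 2413) and 2944 to 5323 in RelA-dTAD (2944, 3223). EV against RelA-WT ran from 59 to 231 (RelA-WT 79 and 77, EV 83 and 59 without replicate 1 and 2), and RelA-dTAD from 28 to 130 (RelA-WT 39 and 44, RelA-dTAD 33 and 28). RelA-dTA1 against RelA-WT ran from 0 to 1 (1 without RelA-dTA1 replicate 2), and against RelA-dTAD from 8 to 37 (RelA-dTA1 14 and 8, RelA-dTAD 9 and 12). Before TNF, EV ran from 16 to 65 (RelA-WT 24 and 44, EV replicate 1 16) and RelA-dTAD from 1 to 6 (1 without its replicate 2). Without RelA-WT replicate 1 and 2, RelA-DB had 22 and 24 (22 to 55), RelA-dCterm 29 and 17 (17 to 48), RelA-TA2_CI-dTA1 6 and 4 (4 to 12) and RelA-TA2_CI_S467A-dTA1 3 and 2 (2 to 11). The dTA1 change ran from 6 to 11 (7 without RelA-dTA1 replicate 1, 6 without RelA-WT replicate 2).

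Of the median NF-kB target differences, that of RelA-TA2_S467A turned to -0.0144 at 1 h alone, and no other sign changed. At 1 h alone RelA-DB was at -1.12, RelA-TA2_CI at -0.556, RelA-TA2_CI_S467A at -0.568, RelA-TA2_CI-dTA1 at -1.31 and RelA-TA2_CI_S467A-dTA1 at -1.21. At 3 h alone RelA-DB was at -1.69, RelA-dCterm at -1.77, RelA-TA2_CI at -0.304, RelA-TA2_CI-dTA1 at -0.975 and RelA-TA2_CI_S467A-dTA1 at -1.19. Against RelA-WT of both sets the medians were -1.25 in RelA-dCterm, -0.348 in RelA-TA2_CI, -0.137 in RelA-TA2_CI_S467A, -0.801 in RelA-TA2_CI-dTA1 and -0.855 in RelA-TA2_CI_S467A-dTA1. A prior count of 0.5 gave -1.11, -0.161 and -0.906 in RelA-dCterm, RelA-TA2_CI_S467A and RelA-TA2_CI-dTA1, and members of at least 5 CPM -1.10, -0.157 and -0.783. Genes chosen in the other set gave -1.34 in RelA-dCterm, -0.331 in RelA-TA2_CI and -0.818 in RelA-TA2_CI_S467A-dTA1.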

Other observations

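The zinc finger test here was chosen after the result was seen. Genes whose symbol is Zfp followed by a digit, most of them DNA-binding repressors, were over-represented among the genes that fell at 1 h of TNF. The set follows names only, so it also takes in Zfp36 of the immediate early list. At that time 30 of the 95 genes that fell in RelA-WT were Zfp genes (31.6%), against 2.58% of all genes tested (odds ratio 19, two-sided Fisher's exact test, p = 6.46e-25, adjusted 1.03e-23), and the blocked fit had 89 of 315. The median log2 change of 352 Zfp genes at 1 h was -0.275 in RelA-WT, -0.225 in RelA-dTA1, -0.193 in RelA-dTAD and -0.187 in EV. By the same exact test they were over-represented in RelA-dTA1, as 15 of 29 fallen genes (p = 6.07e-17, blocked 54 of 189), and in EV, as 4 of 8 (exact p = 2.79e-05, blocked 18 of 63), while in RelA-dTAD they were 1 of 2 (exact p = 0.0509, blocked 15 of 43). At 0.5 h the medians were -0.109 in RelA-WT, -0.0894 in RelA-dTA1, -0.0483 in RelA-dTAD and -0.0595 in EV. Only 5 genes fell in RelA-WT then, 2 of them Zfp genes (exact test, adjusted p = 0.0214), and 3 Zfp genes rose. In each of the other constructs no Zfp gene fell and 2 rose. The blocked fit at 0.5 h had Zfp genes as 10 of 24 fallen genes in RelA-WT, 9 of 22 in RelA-dTA1, 2 of 13 in RelA-dTAD and 4 of 11 in EV. At 3 h the medians were -0.0686 in RelA-WT, -0.0885 in RelA-dTA1, -0.0633 in RelA-dTAD and -0.051 in EV. RelA-dTAD had 7 of 86 fallen genes at 3 h (exact test, adjusted p = 0.0214), though 14 of 692 in the blocked fit. At 8 h the medians were -0.109 in RelA-WT, -0.12 in RelA-dTA1, -0.25 in RelA-dTAD and -0.229 in EV, the latter pair lower than at 1 h. There 98 of 3075 fallen genes were Zfp genes in RelA-dTAD (exact test, adjusted p = 0.0445) and 93 of 3157 in EV (adjusted p = 0.251). In RelA-WT the shares lay below that of all genes tested, with 18 of 785 at 3 h (odds ratio 0.882, adjusted p = 0.895) and 29 of 1582 at 8 h (odds ratio 0.68, adjusted p = 0.103), as in RelA-dTA1 at 8 h, with 47 of 2086 (odds ratio 0.852, adjusted p = 0.528). The others at 3 h were 19 of 665 in RelA-dTA1 and 4 of 126 in EV (adjusted p = 0.82 for both). Many members of the set share sequence, so reads may be assigned among them with error, and such genes are not independent replicates. A fall at 1 h that needs no RelA is consistent with the EV median of -0.187, as a hypothesis from the same data.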
